A study of Homo sapiens with 12 samples.

How the data were processed

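Gene expression was measured by RNA sequencing in SBC5, an established human small cell lung cancer line. Cells received olaparib, an inhibitor of the DNA repair enzymes PARP1 and PARP2, at 1 µM or its solvent dimethyl sulfoxide, and 2 hours later 4 Gy of gamma radiation or none, which makes 4 groups of 3 libraries: vehicle, olaparib, radiation and the combination. RNA was collected after 3 days, and stranded total RNA libraries were sequenced. Per the submitters' processing notes, reads were assigned to transcripts with kallisto 0.46.1 and analysed with DESeq2; the transcriptome release and genome build are not given in the sources used here, so no coordinates are printed. The values deposited are estimated counts per gene (expected counts, with fractions where a read was shared between genes), for 60649 Ensembl gene IDs in 12 columns. Of the values, 68.8% were whole to within 1e-06, and every column summed to a whole number to within 4.5e-08. Totals ran from 14.3 to 38.8 per library, in units of 1e+06 counts. Counts on the 44 rows for pseudoautosomal copies on chromosome Y were added to their X counterparts, which left 60605 genes, and the estimates were then rounded. A gene name table matched 60463 of these IDs, and GENCODE 29 gave a gene type for 58337.

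The comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined, apart from the additions described as made after the data were seen. Each comparison used all 12 libraries in R 4.3.3 with edgeR 4.0.16: the low count filter of edgeR at its defaults over the 4 groups (31858 genes kept), TMM scaling factors, 1 mean per group, robust quasi-likelihood F-tests and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05 on the adjusted p. The series design states 3 comparisons, each treatment against vehicle. Those of the combination with radiation or olaparib, and the interaction, follow from the 2 by 2 design. Log2 fold changes are edgeR's, with its default prior count. Each standard error (SE) is the change over the square root of F, so it depends on the prior count at low counts. Gene values are mean scaled counts per 1e+06 (CPM) with the standard deviation (SD) between libraries. P-values measure the spread between libraries. The sources do not say whether a group's libraries came from separate cultures. The replicate numbers did not pair the libraries.

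Gene lists were written down in advance: chemokines, type I interferon-stimulated genes, antigen presentation, p53 target genes, DNA replication and S phase genes (targets of E2F), G2/M and mitosis, DNA repair and damage checkpoint, senescence-associated cytokines and inflammation, checkpoint and immune ligands, nucleic acid sensing, the PARP family and poly(ADP-ribose) turnover, AU-rich element binding and mRNA decay, translation initiation and control, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, histone genes, the unfolded protein and integrated stress response, cholesterol synthesis, hypoxia and glycolysis, epithelial-mesenchymal transition and matrix, apoptosis regulators, neuroendocrine and subtype markers of small cell lung cancer, and markers of leukocytes, fibroblasts, endothelium, and airway and alveolar epithelium. Of the listed symbols, AUF1 alone was not found in the name table. Each list was compared with all other tested genes by camera in limma 3.58.1 with a preset correlation between genes of 0.01, and again with the correlation estimated from the data, with Benjamini-Hochberg adjustment over the 26 lists of a comparison. For each list the number of members past the threshold is given over all genes tested and adjusted over the list alone. Genes were named by a rule: in each comparison the 5 largest rises and 5 largest falls among called genes with a symbol, at least 1 CPM in the higher group and libraries that did not overlap between the groups (a condition that chance meets in 10% of genes with 3 libraries against 3); called members of the lists with the largest change; and PARP1, CD274, CDKN1A, CCL5, CXCL10, STING1, CGAS and IFNB1 whatever their values. Non-overlap was not asked of the interaction. A gene outside this rule is named as chosen after its values were seen.

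Alternatives fixed in advance were DESeq2's size factors in edgeR, library size only, no count filter, a stricter filter (1 CPM in at least 3 libraries), DESeq2 1.42.0, limma-voom, the libraries of the compared groups alone, the replicate number as a block, each library left out in turn, mitochondrial and small structural RNA genes left out, and a log2 change of at least 1. The following were added after the data were seen. Libraries whose summed CPM over 381 olfactory receptor genes was more than 1.5 times the median of the 12 were set aside, which removed 3 libraries and left 9 (3 vehicle, 1 olaparib, 2 radiation and 3 combination; 30967 genes tested). All alternatives fixed in advance and the list tests were repeated on these 9 libraries, where the lone olaparib library is assumed to vary like the other groups. The log2 of the olfactory receptor sum was also used as a covariate with all 12 libraries, and transcript length and GC content were used as offsets. The common biological coefficient of variation was 0.624 in the 12 libraries and 0.379 in the 9, and TMM factors ran from 0.84 to 1.48 and from 0.916 to 1.09. An alternative fixed in advance for files of normalized values was not run, since the file holds counts.

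The fits were tested on simulated data of equal size, with 67 or 66 genes changed at each of 3 folds. Each gene's spread was the same in all libraries, without the shift of the 3 set aside, so the 12-library rates may not apply. Recovery was not split by expression level. In combination versus vehicle with 12 libraries, edgeR recovered 0%, 2.99% and 47% of genes changed 1.5-fold, 2-fold and 4-fold. Of its 35 calls, 2 were unchanged genes. With 9 libraries it recovered 31.3%, 46.3% and 80.3% (13 of 118 calls unchanged). DESeq2 with 12 libraries called 46 unchanged genes among 98. In olaparib versus vehicle with 9 libraries, edgeR recovered 10.4%, 34.3% and 65.2%. Shares of counts have 95% Wilson intervals, and a count of 0 is read as allowing up to 3 per library. Both cover counting error only. A fold against a group at 0 is given as a bound from that floor, since the fitted value depends on the prior count.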

Results

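RNA was sequenced from SBC5 cells 3 days after treatment. The 12 libraries were 3 each of vehicle, olaparib (1 µM), radiation (4 Gy) and olaparib 2 hours before radiation, called the combination. Total counts of libraries 1, 2 and 3, in units of 1e+06, were 27, 33.7 and 34.1 in vehicle and 38.8, 17.7 and 16.2 in olaparib. They were 30, 26.9 and 14.3 in radiation and 19.4, 20.6 and 19.6 in the combination.

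In 3 libraries, many genes that are silent or nearly silent in the other 9 carried counts. The summed CPM of 381 olfactory receptor genes, which most tissues do not express, was 1875 in olaparib 2, 2079 in olaparib 3 and 914.5 in radiation 3, against 354 to 500.9 in the other 9 libraries. PCSK5, which encodes a protease that processes precursor proteins, took 3.37% of the counts in olaparib 2 (95% Wilson interval 3.36% to 3.38%), 3.28% in olaparib 3 (3.27% to 3.29%) and 1.17% in radiation 3 (1.17% to 1.18%). Its share elsewhere reached 0.14% at most, in vehicle 1 (0.138% to 0.141%). The first principal component held 60.7% of the variance. It set the 3 libraries (159 to 272) apart from the 9 (-102 to -40.1). Vehicle 1 lay nearest to the 3 on it (-40.1), and after group means were taken out its expression correlated with that of the 3 (r = 0.246, 0.227 and 0.241), though its olfactory receptor sum (431.7) was within the range of the 9. The labels name no batch that these libraries share. Each has partners of the same treatment among the 9, so this difference lies inside the olaparib and radiation groups.

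**Figure D1:**
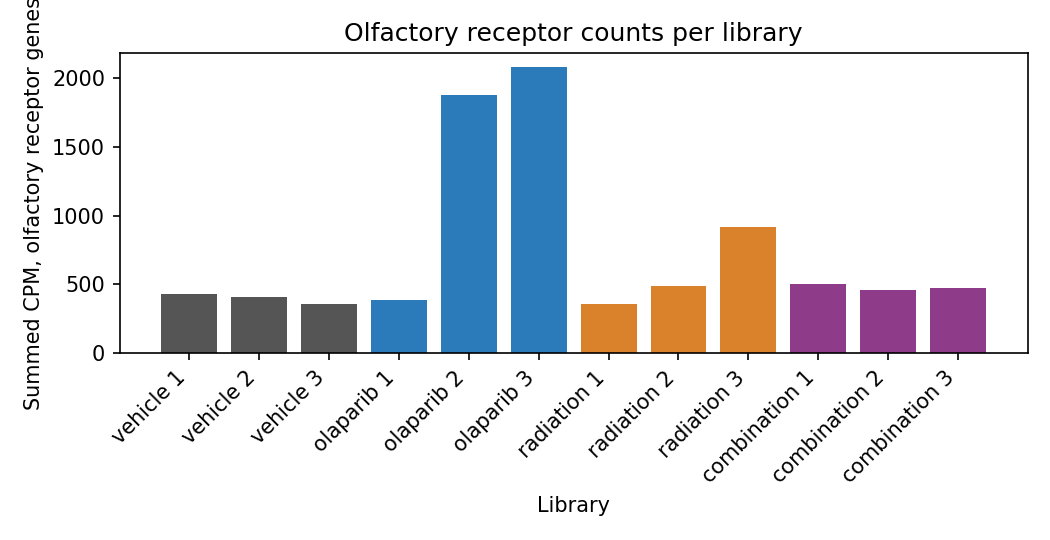
Bars give the summed CPM over 381 olfactory receptor genes in each of the 12 libraries. Olaparib 2 (1875), olaparib 3 (2079) and radiation 3 (914.5) stand above the other 9 (354 to 500.9).

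With all 12 libraries, edgeR with Benjamini-Hochberg adjustment over 31858 genes called 1 gene in combination versus vehicle: IGF2, which encodes insulin-like growth factor 2. Its level was 39 CPM (SD 2.87, n = 3) in the combination and 13.7 CPM (SD 0.897, n = 3) in vehicle (log2 change 1.51, SE 0.193, adjusted p = 0.0418). Against olaparib, 3 genes were higher in the combination and none lower. They were IGF2 (log2 1.76, SE 0.195, adjusted p = 0.00675), the noncoding RNA LINC01001 (1.69, SE 0.239, adjusted p = 0.0452) and SLC7A5, which imports large neutral amino acids (1.56, SE 0.22, adjusted p = 0.0452). SLC7A5 had 12.5 CPM in vehicle, 7.88 in olaparib, 15.7 in radiation and 23.3 in the combination. The IGF2 call against vehicle was lost without vehicle 1, 2 or 3, radiation 1 or 2 or combination 1, 2 or 3 (adjusted p = 0.0807 to 1), with log2 changes of 1.45 to 1.56 in these fits. Against olaparib its call was lost without combination 1 (adjusted p = 0.0601). The calls of SLC7A5 and LINC01001 were lost without any of the vehicle or combination libraries, radiation 1, radiation 2 or olaparib 3, and that of SLC7A5 without olaparib 2 (adjusted p = 0.065 to 0.291).

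The other 4 comparisons had 0 genes past the threshold by edgeR in the 12 libraries. At an unadjusted p under 0.05 there were 1262 genes in combination versus vehicle, 1358 in radiation versus vehicle, 9369 in olaparib versus vehicle, 1044 in combination versus radiation, 8661 in combination versus olaparib and 7747 for the interaction. In that order, DESeq2 called 98, 26, 3762, 4, 3703 and 1792 genes, and limma-voom called 0 except for 1 in combination versus olaparib. Olaparib 1 decided most of these counts. Without it, so that the olaparib group held olaparib 2 and olaparib 3 alone, edgeR called 240 genes in combination versus vehicle, 59 in radiation versus vehicle, 18110 in olaparib versus vehicle, 0 in combination versus radiation, 17267 in combination versus olaparib and 16020 for the interaction. Without radiation 3 the counts in that order were 4, 1, 32, 2, 86 and 3. The median log2 change over all genes was 0 in combination versus vehicle, 0.12 in radiation versus vehicle, 0.39 in olaparib versus vehicle, -0.09 in combination versus radiation, -0.33 in combination versus olaparib and -0.39 for the interaction. With library size only, these medians became 0.20, 0.31, 0.97, -0.07, -0.71 and -0.96.

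Among the 26 gene lists, camera with the preset correlation called 6, 7, 18, 0, 15 and 17 in the same order of comparisons with 12 libraries, and none of these calls held with an estimated correlation. The smallest adjusted p with an estimated correlation was 0.0699, for mitochondrially encoded mRNAs in combination versus vehicle. The chemokine list, which the study's title points to, had a median log2 of 3.53 in olaparib versus vehicle (0 of 13 members higher over all genes, 4 adjusted over the list alone; adjusted p = 0.0325, and adjusted p = 0.432 with an estimated correlation). It was not called with library size only, the stricter count filter or the background covariate (adjusted p = 0.132, 0.0837 and 0.957). Among its members, CXCL12 had 78, 67 and 12 counts in olaparib 2, olaparib 3 and radiation 3 and 0 in the other 9. CCL22 had 96, 151 and 43 against 0 to 21. CCL28 had 188 to 328 counts in every library. Setting the 3 libraries aside changed the sign of the median for 11 of the lists called in either fit in olaparib versus vehicle, 11 in combination versus olaparib and 15 for the interaction, against 0 in combination versus vehicle, 1 in radiation versus vehicle and 3 in combination versus radiation. For this reason, chosen after seeing the data, the biology is described with the 9 libraries with olfactory receptor sums of at most 500.9 CPM, beside the planned fits.

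Combination versus vehicle asks what olaparib and radiation together changed. In the 9 libraries, the mRNAs encoded by the mitochondrial genome were lower in the combination: 12 of 13 passed over all genes and 13 adjusted over the list alone, with a median log2 of -0.90 (camera adjusted p = 5.48e-87, and adjusted p = 0.000223 with an estimated correlation). MT-ND3, a subunit of respiratory complex I, stood at 140 CPM (SD 4.63, n = 3) against 355 (SD 9.54, n = 3) in vehicle (log2 -1.34, SE 0.0694, adjusted p = 9.2e-26). Histone mRNAs were lower as well, 12 of 18 over all genes and 14 adjusted over the list alone (median -0.64, adjusted p = 3.87e-22, and adjusted p = 0.0443 with an estimated correlation). Among them was the linker histone H1-2, at 23.6 CPM (SD 4.57, n = 3) against 52.9 (SD 5.66, n = 3). Of the cholesterol synthesis genes, 10 of 23 were lower over all genes and 14 adjusted over the list alone (median -0.36, adjusted p = 3.39e-14, and adjusted p = 0.0443 with an estimated correlation). Of the mRNAs for cytosolic ribosomal proteins, 33 of 42 were lower over all genes and 38 adjusted over the list alone, with a median of -0.39 (adjusted p = 2.06e-41, but adjusted p = 0.0795 with an estimated correlation). These 4 lists kept a negative median under every scaling tried. With library size only the medians were -0.70 (mitochondrial), -0.44 (histone), -0.16 (cholesterol) and -0.18 (ribosomal).

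The unfolded protein and integrated stress response list moved both ways in this comparison, with 7 members higher and 2 lower of 22 over all genes, and 11 and 2 adjusted over the list alone (median 0.27, adjusted p = 3.61e-07, but adjusted p = 0.207 with an estimated correlation). ATF3, a transcription factor induced by stress, rose most, from 2.42 CPM (SD 0.95, n = 3) to 8.4 (SD 1.39, n = 3; log2 1.79, SE 0.274, adjusted p = 1.53e-06). Of its other called members, picked after their values were seen, ASNS (log2 0.91), PSAT1 (1.13), SLC7A11 (0.96) and STC2 (0.95), which serve amino acid supply and stress signalling, rose. The chaperones HSPA5 (-0.69) and HSP90B1 (-0.37) fell. SLC7A5 rose with an adjusted p of 2.59e-05 (log2 0.90, SE 0.157) and IGF2 with one of 1.74e-14 (log2 1.51, SE 0.133). BRCA1 and BRCA2, which act in homologous recombination, rose by log2 changes of 0.51 (SE 0.0868, adjusted p = 2e-05) and 0.66 (SE 0.0818, adjusted p = 5.3e-09). BRCA2 went from 85.6 CPM (SD 9.99) to 135 (SD 10.4, n = 3 each). CENPF, a kinetochore protein, rose (0.49, SE 0.0617), as did the translation factor EIF5 (0.64, SE 0.0808), the Notch target HES1 (1.44, SE 0.246) and the p53 target AEN (1.01, SE 0.213). PARP1, the target of olaparib, was lower (-0.35, SE 0.0762, adjusted p = 0.0012), a call that ended with library size only (adjusted p = 0.266) and with the background covariate.

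Of 30967 genes tested in the 9 libraries, edgeR called 475 higher and 1010 lower in the combination than in vehicle, with 4445 at an unadjusted p under 0.05. Called changes had a median size of 0.466 on the log2 scale, and 82 higher and 53 lower genes changed by at least 1. DESeq2 called 575 higher and 1105 lower and limma-voom 428 and 903. The planned fit to the 6 libraries of these groups alone called 523 higher and 971 lower of 23003 genes, of which 455 and 944 were shared with the 9-library calls. With all 12 libraries and the olfactory receptor sum as a covariate, 457 were higher and 374 lower, of which 369 and 318 were shared. The balance of directions followed the scaling: with library size only, which moved the median of all genes from 0.02 to 0.22, 2275 were higher and 319 lower.

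**Figure D2:**
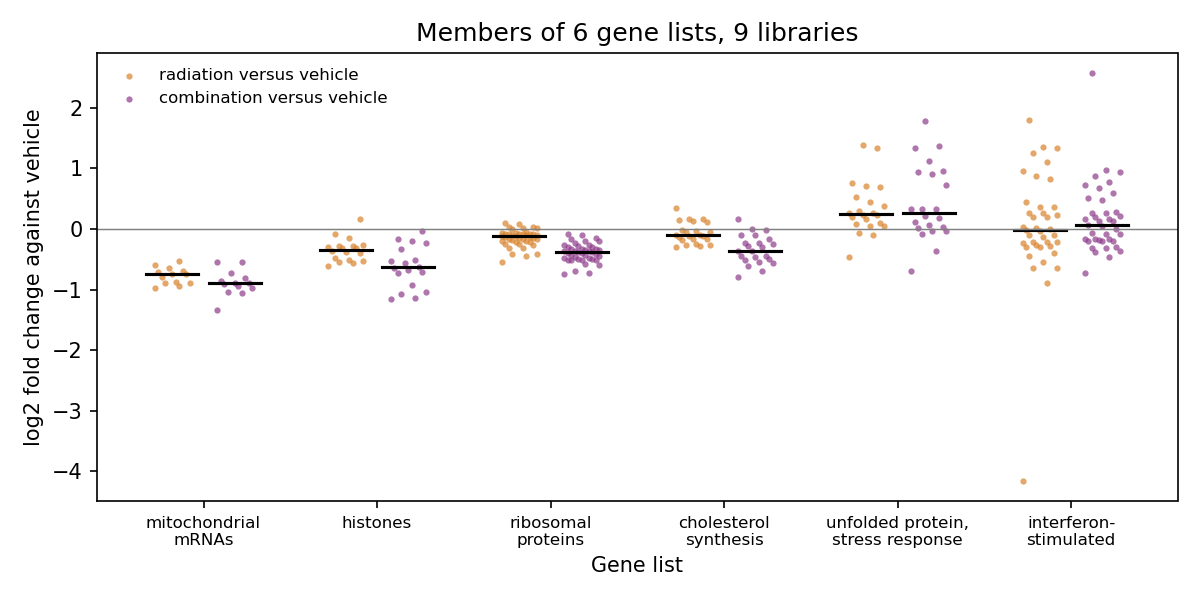
Each point is a member of 1 of 6 gene lists, placed by its log2 change against vehicle in the 9 libraries, for radiation and for the combination, with a bar at the median. Mitochondrially encoded mRNAs have the lowest medians of the 6 lists (-0.75 and -0.90), while those of interferon-stimulated genes are near 0 (-0.02 and 0.06).

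By size of change, the rises against vehicle with the lead were PHKA1P1 (log2 4.57, SE 0.948, a pseudogene whose reads can belong to its parent PHKA1), GJA9 (4.11, SE 0.845), the circadian repressor BHLHE41 (3.71, SE 0.717) and ELMOD1 (3.38, SE 0.629), all at 1.48 to 2.45 CPM in the combination. GK3 (4.66, SE 1.24, adjusted p = 0.0117; 3 counts in vehicle, ratio 30, 95% counting interval 9.81 to 149), a copy of the glycerol kinase gene GK, lost its call without vehicle 2, vehicle 3 or combination 3 (adjusted p = 0.0726, 0.0781 and 0.168). The fructose transporter SLC2A5 fell from 5.73 CPM (SD 1.32) to 0.76 (SD 0.475, n = 3 each; log2 -2.90, SE 0.406, adjusted p = 1.28e-06), and the mitochondrial transfer RNA MT-TS1 fell by 2.69 (SE 0.39). Y_RNA (-4.06, SE 0.971) lost its call without vehicle 1 (adjusted p = 0.0553), SPATA1 (-4.00, SE 0.951) without vehicle 2 (0.0518) and MAP7-AS1 (-2.38, SE 0.521) without vehicle 1 (0.232). Every library of the combination lay on 1 side of every vehicle library for each of these 10 genes, a condition of the rule that named them, which chance meets in 10% of genes. Abundant genes with small p-values, picked after their values were seen, were TMSB4X, which binds actin monomers (log2 -0.97, SE 0.065, from 672 to 343 CPM), the transcription factor SOX2 (-0.82, SE 0.0647), the glutamate receptor GRIA2 (-0.93, SE 0.0758), the growth factor HGF (-0.88, SE 0.0751), the gap junction gene GJA1 (-0.80, SE 0.0678) and the protease CTSK (-0.82, SE 0.07), all lower.

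**Figure D3:**
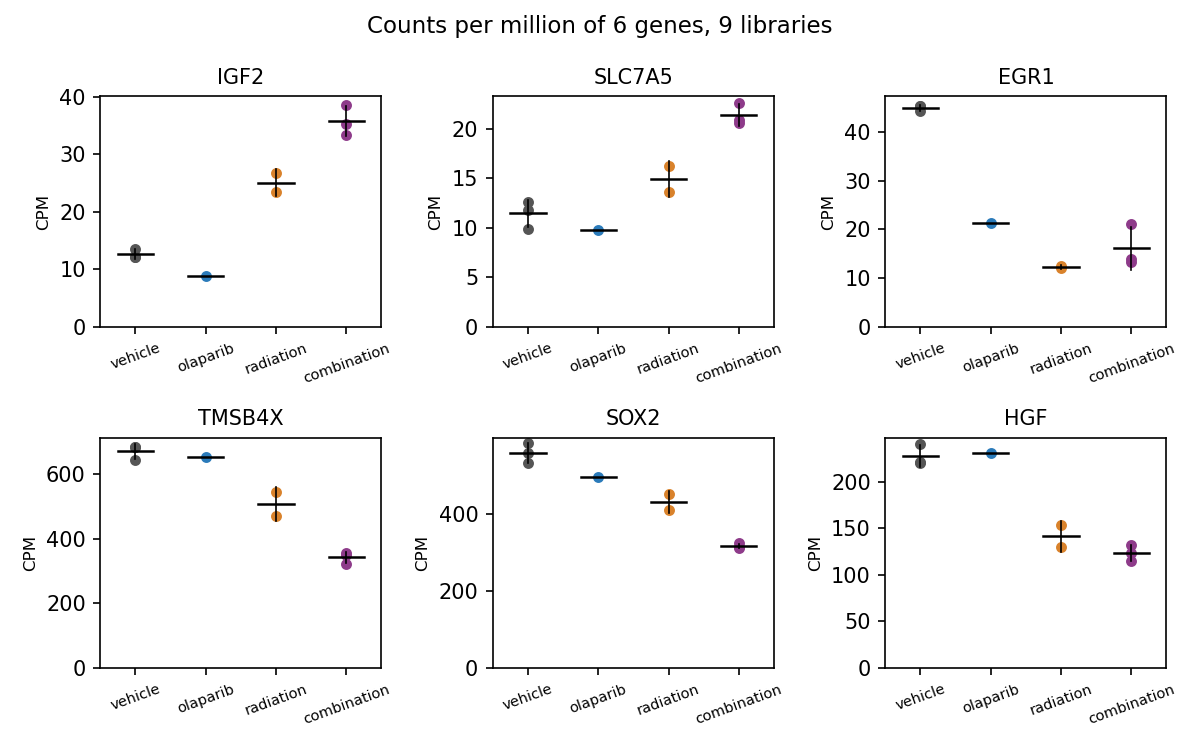
Points are scaled CPM of 6 genes in each of the 9 libraries by treatment, lines are group means and bars are SDs (olaparib has 1 library). IGF2 rises from a mean of 12.6 in vehicle to 25.1 in radiation and 35.7 in the combination, and TMSB4X falls from 672 to 508 and 343.

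Chemokines, the genes closest to the study's title, showed no called change in the combination: of 27 listed, 8 had enough counts to test in the 9 libraries and edgeR called 0 (0 adjusted over the list alone; median 0.13, mean -0.17, camera direction down, adjusted p = 0.977). CCL28 was the most abundant (11.8 CPM, SD 1.08, against 9.29, SD 0.859, n = 3 each; log2 0.34, SE 0.186, adjusted p = 0.42), and CCL22 changed by -2.30 (SE 1.48, adjusted p = 0.541) below 0.5 CPM. CCL5, a chemokine that draws T cells, stood at 0.223 CPM against 0.182 (log2 0.28, SE 1.41, adjusted p = 0.979). CXCL10 had 0 counts in each of the 9 libraries, which allows up to 0.0788 to 0.146 CPM by library. IFNB1 was below the count filter, so changes at those levels were not detectable at this depth. CD274, which encodes PD-L1, changed by 1.95 (SE 1.8, adjusted p = 0.753) from 0.0638 CPM. The sensor CGAS changed by 0.22 (SE 0.111, adjusted p = 0.352). Its partner STING1 changed by 2.45 (SE 1.24, adjusted p = 0.353) at under 1 CPM and passed without vehicle 1 (0.0257). The cell cycle inhibitor CDKN1A changed by 1.57 (SE 0.519, adjusted p = 0.0649), from 0.761 CPM (SD 0.256) to 2.26 (SD 0.493), and passed without radiation 2 (0.046). RNA counts do not measure translation, which the title names.

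Among the other immune and damage response lists in this comparison, none was called by camera in the 9-library fit, and 4 were called in other settings. With library size only, p53 targets (median 0.252, adjusted p = 0.0172), G2/M genes (0.176, adjusted p = 0.000149) and DNA repair genes (0.212, adjusted p = 0.000718) were called. The same 3 were called with the background covariate (0.145, 0.0763 and 0.101; adjusted p = 0.0145, 0.00102 and 0.0209), and checkpoint ligands with the stricter count filter (-0.256, adjusted p = 0.0258). Interferon-stimulated genes had 1 of 39 members lower over all genes and 0 adjusted over the list alone (median 0.06, adjusted p = 0.977). Antigen presentation had 2 of 22 lower, 2 over the list alone (median 0.10 with the test pointing down, adjusted p = 0.608). Of these, TAPBP, a peptide loading chaperone, fell by 0.65 (SE 0.136). The p53 targets had 1 higher and 1 lower of 32, and 6 and 3 over the list alone (median 0.05, adjusted p = 0.276). DNA replication genes had 1 higher and 2 lower of 43, 2 and 3 over the list alone (0.06, adjusted p = 0.949). Among the lower was TYMS, which makes thymidylate (-0.57, SE 0.116). G2/M genes had 2 higher and 1 lower of 45, 2 and 2 over the list alone (-0.02, adjusted p = 0.949). DNA repair genes had 3 higher and 4 lower of 41, 4 and 5 over the list alone (0.01, adjusted p = 0.729). Senescence-associated cytokines had 0 of 28 (median 0.28, adjusted p = 0.132), with VEGFA (0.25, SE 0.0913, adjusted p = 0.106) and SERPINE2 (0.43, SE 0.228, adjusted p = 0.409) closest. Checkpoint ligands had 3 of 22 lower, 3 over the list alone (median -0.08, mean 0.02, adjusted p = 0.202). Nucleic acid sensing had 2 of 17 lower, 2 over the list alone (0.09, adjusted p = 0.919), and the PARP family had 3 of 22 lower, 3 over the list alone (-0.02, adjusted p = 0.606).

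Of the remaining lists, 3 were called by the preset test only, each with a sign that flipped under library size only and a call lost with the covariate (AU-rich element binding -0.0392, adjusted p = 0.286; translation initiation -0.0227, 0.755; hypoxia 0.0261, 0.544). AU-rich element binding genes had 7 of 27 lower, 1 higher and 9 lower over the list alone (median -0.13, adjusted p = 3.27e-05, but adjusted p = 0.14 with an estimated correlation; 0.07 with library size only). Its leading member was ZFP36L1 (-0.82, SE 0.0961, adjusted p = 9.61e-10), which marks mRNAs for decay. Translation initiation genes had 1 higher and 8 lower of 29, 1 and 11 over the list alone (-0.15, adjusted p = 0.000484, but adjusted p = 0.462 with an estimated correlation; 0.05 with library size only). This call was also lost without vehicle 3 (adjusted p = 0.0649) and with all 12 libraries (0.0831). Hypoxia and glycolysis genes had 7 of 24 lower, 2 higher and 10 lower over the list alone (median -0.08, mean 0.02, adjusted p = 0.000168, but adjusted p = 0.292 with an estimated correlation; 0.12 with library size only; 0.112 for the p with all 12 libraries). Its leading member was PGAM1 (-0.50, SE 0.0874). Matrix and epithelial-mesenchymal transition genes had 4 of 26 lower, 4 over the list alone (median 0.06 with the test pointing down, adjusted p = 0.193). Leading it was CCN2 (-0.81, SE 0.071, adjusted p = 1.21e-14), a target of YAP. Apoptosis regulators had 1 higher and 2 lower of 25, 2 and 2 over the list alone (0.05, adjusted p = 0.679). Neuroendocrine markers had 2 higher and 3 lower of 18, 2 and 4 over the list alone (-0.06, adjusted p = 0.345). Markers of leukocytes (0 of 8, median 0.66, adjusted p = 0.345) and fibroblasts (1 of 12 lower and 1 over the list alone, PDGFRA at -0.51, SE 0.0821; median -0.30, adjusted p = 0.512) were not called. Neither were those of endothelium (0 of 8, -0.19, adjusted p = 0.679) or airway epithelium (0 of 7, -0.05, adjusted p = 0.825). MSMO1 led the cholesterol genes (-0.79, SE 0.136) and RPL27 the ribosomal ones (-0.74, SE 0.0868), whose many processed pseudogenes share sequence with them.

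Further list members passed in this comparison but lost their call when 1 library was left out. MX2 (log2 -0.32, adjusted p = 0.0485), an interferon-induced antiviral gene, lost it without vehicle 2 or 3, olaparib 1 or combination 1 or 3 (0.0606 to 0.3). The chaperone CALR (-0.26) lost it without vehicle 2 (0.0662) or combination 3 (0.0572), and cyclin G1, CCNG1 (-0.27), without vehicle 2 (0.192) or combination 2 (0.0694). The cyclin genes CCNE2 (0.73) and CCNA2 (-0.32) lost it without vehicle 2 (0.053 and 0.215). CCNE2 also lost it without combination 3 (0.0694), and CCNA2 also without vehicle 1 or combination 1 or 2 (0.0677 to 0.147). The T cell costimulator CD70 (-0.61) lost it without vehicle 2 or 3 or combination 1 or 2 (0.0528 to 0.143). ENPP1, which degrades the cGAS product (-0.48), lost it without vehicle 1, 2 or 3 or combination 2 or 3 (0.0751 to 0.237). HPF1, which directs PARP1 to serine residues (-0.52), lost it without vehicle 1 or 2 or combination 1, 2 or 3 (0.0763 to 0.225). The apoptosis gene PMAIP1 (0.70) lost it without vehicle 2 or 3 or combination 3 (0.0609 to 0.229). Of 37 genes named by the rule and called in this comparison, 24 kept the call in every such fit.

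Radiation versus vehicle asks what 4 Gy alone changed, and the 9 libraries hold 2 radiation libraries. Mitochondrially encoded mRNAs were lower here too, 12 of 13 over all genes and 13 adjusted over the list alone (median log2 -0.75, adjusted p = 8.5e-81, and adjusted p = 0.000329 with an estimated correlation). They made up 3.12% of all counts in radiation (SD 0.11, n = 2), 3.08% in the combination (SD 0.024, n = 3) and 4.93% in vehicle (SD 0.13, n = 3). EGR1, an early response transcription factor, fell by 1.88 (SE 0.157, adjusted p = 9.29e-14), from 45 CPM to 12.2, and IGF2 rose by 0.99 (SE 0.144, adjusted p = 2e-06). Both were picked after their values were seen. The cyclin CCND2 rose from 0.904 CPM (SD 0.234, n = 3) to 3.68 (SD 0.739, n = 2; log2 2.02, SE 0.385, adjusted p = 0.000514), and TAPBP fell by 0.95 (SE 0.155, adjusted p = 3e-05). Of the stress response genes, 6 were higher and 1 lower of 22 over all genes, and 8 and 1 over the list alone (median 0.25, adjusted p = 9.98e-10, but adjusted p = 0.339 with an estimated correlation).

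Over all genes, edgeR called 130 higher and 210 lower of 30967 in radiation versus vehicle (2997 at an unadjusted p under 0.05; DESeq2 231 and 255, limma-voom 195 and 248), with 200 in all without vehicle 2. With the covariate and 12 libraries it called 123 and 71. Under library size only, 560 were higher and 125 lower, so the balance of directions followed the scaling here as well. Histone genes had 0 members called over all genes and 9 lower over the list alone (median -0.34, adjusted p = 3.19e-07, but adjusted p = 0.343 with an estimated correlation). Ribosomal protein genes had 2 lower over all genes and 7 over the list alone (median -0.12, adjusted p = 1.51e-06, but adjusted p = 0.592 with an estimated correlation). That call was lost without radiation 2 (median -0.04, adjusted p = 0.55) and with the covariate (-0.0281, adjusted p = 0.212). Under library size only the median was -0.01. G2/M genes had a median of 0.08 (adjusted p = 0.00198, but adjusted p = 0.598 with an estimated correlation), lost without radiation 1 (adjusted p = 0.803). CENPF was higher by 0.33, and it also lost its call without radiation 1 (0.0932). The p53 targets had 0 called over all genes and 3 higher over the list alone (median 0.17, adjusted p = 0.0477, but adjusted p = 0.592 with an estimated correlation). That list call was lost without vehicle 1 or 2, olaparib 1, radiation 1 or 2 or combination 2 or 3 (0.0511 to 0.177), with the stricter count filter (0.119) and with structural RNA left out (0.0519). The other 20 lists, chemokines included, were not called in the 9-library fit. In other settings, DNA replication genes were called as higher with library size only (0.211, adjusted p = 0.00863), the covariate (0.141, adjusted p = 0.0079) and without radiation 2 (0.184, adjusted p = 0.000695). Hypoxia genes were called as higher in the same 3 settings (adjusted p = 0.0317, 0.04 and 0.0488), and DNA repair genes with library size only and the covariate (0.0108 and 0.04). Translation initiation genes were called as lower without vehicle 1 or radiation 1 (0.0209 and 0.0108) and cholesterol genes without radiation 1 (0.0388). Translation initiation, cholesterol and AU-rich element binding genes were called as lower with all 12 libraries (adjusted p = 0.000811, 0.000809 and 0.000219). Taking radiation 1 out of the 12, which gives radiation 3 more weight, called G2/M (-0.107, adjusted p = 0.00061), DNA replication, DNA repair, hypoxia, PARP family and antigen presentation genes as lower (0.00153 to 0.0186 for the last 5). Chemokines (2.53, adjusted p = 0.0251), senescence-associated cytokines and the leukocyte, endothelial and airway markers were then called as higher (0.0124 to 0.047). Chemokines and leukocyte markers were also called among the 12 without radiation 2 (0.022 each) or with no count filter (0.0371 each).

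The rises against vehicle that led by size after radiation were GJA9 (log2 3.93), ARHGEF6 (2.56), CCND2, PSMD7-DT (1.75) and CD24 (1.68). The falls were SORD2P (-6.14, SE 0.811, adjusted p = 1.65e-07, a pseudogene of SORD), FHAD1-AS1 (-4.75), the pseudogene SLC26A10P (-4.11), the carnitine transporter SLC22A16 (-3.96) and MT-TS1 (-2.82, SE 0.453). All of these were below 4 CPM except MT-TS1. SORD2P and FHAD1-AS1 had 2 counts each in radiation, so their log2 values depend on the prior count. Their ratios were 0.0123 and 0.0339, with 95% counting intervals, which leave out the spread between libraries, of 0.00148 to 0.0449 and 0.00405 to 0.126. The SORD2P call was lost with all 12 libraries (adjusted p = 0.67). GJA9 lost its call without vehicle 3 or radiation 1 (adjusted p = 0.0532 and 0.0612), ARHGEF6 and FHAD1-AS1 without vehicle 2 (0.058 each) or radiation 2 (0.158 and 0.143), and SLC22A16 without radiation 2 (0.127). CD24 lost it without vehicle 2 or 3 or radiation 1 (0.173, 0.0944 and 0.333), and SLC26A10P without vehicle 2 or 3 or radiation 1 or 2 (0.0759 to 0.336). PSMD7-DT lost it without vehicle 1, 2 or 3, olaparib 1, radiation 1 or 2 or combination 2 (0.0511 to 0.332). TYMS fell by 0.54 (adjusted p = 0.0137) and lost its call without vehicle 2, radiation 1 or radiation 2 (0.118 to 0.14). BRCA2 rose by 0.34 (adjusted p = 0.0368), lost without vehicle 1 or 3, olaparib 1, radiation 1 or 2 or combination 3 (0.0511 to 0.318). Genes named whatever their values were not called: PARP1 -0.25 (SE 0.0854, adjusted p = 0.19), CGAS 0.22 (SE 0.123, adjusted p = 0.579), CDKN1A 0.67 (SE 0.57, adjusted p = 0.798), CD274 1.82 (SE 1.92, adjusted p = 0.858), STING1 0.59 (SE 1.36, adjusted p = 0.957) and CCL5 0.62 (SE 1.53, adjusted p = 0.962).

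Olaparib versus vehicle rests on olaparib 1 alone in the 9 libraries, so its p-values borrow the spread of the other groups. EGR1 was lower, at 21.3 CPM against 45 (SD 0.627, n = 3) in vehicle (log2 -1.08, SE 0.194, adjusted p = 0.00196). Lower too was the ribosomal protein gene RPS16 (-1.30, SE 0.148, adjusted p = 1.7e-08). So was ACSM2B, an acyl-CoA synthetase with a close paralog (-2.80, SE 0.512, adjusted p = 0.00179), although with all 12 libraries its change was 1.19 (adjusted p = 0.307), and lower again with the covariate (adjusted p = 0.031). NUDT4B, a close copy of NUDT4, was higher (2.95, SE 0.535, adjusted p = 0.00179), with 5.49 CPM against 0.702 (SD 0.324, n = 3). Mitochondrially encoded mRNAs had a median log2 of -0.27, with 3 of 13 called over all genes and 8 adjusted over the list alone (adjusted p = 7.16e-13, and adjusted p = 0.0279 with an estimated correlation). They made up 4.23% of the counts of olaparib 1 (95% Wilson interval 4.22% to 4.23%). The purine synthesis gene ATIC (-1.05) lost its call without vehicle 3 (adjusted p = 0.0712), and RNF26 (-1.01) without vehicle 1, 2 or 3 (0.127, 0.114 and 0.0784).

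In all, edgeR called 3 genes higher and 18 lower in olaparib 1 (1034 at an unadjusted p under 0.05; DESeq2 2 and 38, limma-voom 11 and 35), and 33 in all without vehicle 3. The covariate fit to 12 libraries called 0 and 10. PARP1 (0.05, SE 0.107), CGAS (-0.03, SE 0.155), CDKN1A (0.47, SE 0.705), CD274 (1.22, SE 2.31), STING1 (2.10, SE 1.52) and CCL5 (1.43, SE 1.8) all had an adjusted p of 1. G2/M genes (median 0.09, adjusted p = 0.00975) and ribosomal protein genes (0.10, adjusted p = 0.0129) were called by the preset test, with adjusted p = 0.883 and 0.917 with an estimated correlation. With all 12 libraries both had the opposite sign and were called (-0.50, adjusted p = 1.36e-13, and -0.58, adjusted p = 1.01e-15). Both kept the 9-library sign with the covariate but were not called (0.0321 and 0.0386; adjusted p = 0.284 and 0.206). Neither was called with the length offset (0.0906 and 0.259), the GC offset (0.0742 each) or without vehicle 1 (0.0615 and 0.336), nor ribosomal genes with structural RNA left out (0.0521). The other 23 lists were not called in the 9-library fit. In other settings histone genes were called as higher with library size only (0.00733), no count filter (0.0432), the replicate block (0.0243) and without vehicle 3 (0.00562), as were p53 targets (0.0108, 0.0352, 0.0237 and 0.0198). Stress response genes were called as higher with library size only (0.0487), the block (0.0243) and without vehicle 3 (0.0189), DNA replication and hypoxia genes in the first and last of these (0.00619 to 0.0295), and DNA repair genes with library size only (0.0199). These 6 lists were called as lower with all 12 libraries.

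Combination versus radiation asks what olaparib added to radiation. Cholesterol synthesis genes were lower with olaparib, 5 of 23 over all genes and 10 adjusted over the list alone (median log2 -0.26, adjusted p = 2.2e-12, but adjusted p = 0.173 with an estimated correlation). INSIG1, which restrains the pathway's activation, was among them (-0.57), picked after its value was seen. Ribosomal protein genes had 10 of 42 lower over all genes and 29 over the list alone (median -0.26, adjusted p = 9.57e-22, but adjusted p = 0.216 with an estimated correlation). MT-ND3 was the only mitochondrially encoded mRNA called (-0.37, SE 0.076, adjusted p = 0.00321), with 5 over the list alone and a list median of -0.15 (adjusted p = 0.0028, but adjusted p = 0.216 with an estimated correlation). With library size only that median was -0.0577 and the list was not called (adjusted p = 0.37). The Golgi enzyme MGAT2 differed (log2 3.07, SE 0.358, adjusted p = 7.23e-08), with radiation low: 7.07 CPM (SD 2.96, n = 3) against 0.84 (SD 0.0568, n = 2), with 5.73 in vehicle and 10.6 in olaparib 1. The change was 1.01 (adjusted p = 1) with all 12 libraries and 1.10 (adjusted p = 0.867) with the covariate. SLC2A5 was lower (-2.60, SE 0.43, adjusted p = 0.000331). UQCC6, an assembly factor of respiratory complex III, was lower too (-0.90, SE 0.18, adjusted p = 0.00233).

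Of all genes, edgeR called 44 higher and 132 lower in combination versus radiation (2954 at an unadjusted p under 0.05; DESeq2 50 and 373, limma-voom 37 and 165; 6 and 22 with the covariate). The total of 176 rested on single libraries: it was 38 without radiation 1, 447 without radiation 2, and 116 without olaparib 1 or without combination 2. Under library size only, 142 were higher and 58 lower. Histone genes (2 lower, 7 over the list alone, median -0.28, adjusted p = 1.76e-07) and hypoxia genes (3 lower, 8 over the list alone, -0.18, adjusted p = 8.66e-07) were called by the preset test, each with adjusted p = 0.216 with an estimated correlation. So were G2/M genes (-0.12, adjusted p = 0.000931), AU-rich element binding genes (-0.07, adjusted p = 0.0221; 0.02 with library size only) and translation initiation genes (-0.09, adjusted p = 0.0363), with adjusted p = 0.656, 0.424 and 0.805 with an estimated correlation. These 3 calls were lost without radiation 1 (adjusted p = 0.803, 0.239 and 0.945), which left 5 of 8 lists called. None of the 3 was called with library size only (0.384, 0.834 and 0.852) or the covariate (0.12, 0.605 and 0.623), and translation initiation was not called without combination 1 (0.0955) or with the stricter count filter (0.0676). Other lists gained a call when 1 library was left out: DNA replication genes without radiation 2 or combination 2 (0.000804 and 0.0273), the PARP family without radiation 2 (0.0125) and leukocyte markers without combination 1 or 2 (0.0277 and 0.0273). No list was called with all 12 libraries. Among the other rises, SORD2P (5.83, SE 0.814) kept its call when 1 library was left out but not with limma-voom (0.0764) or all 12 libraries (1), while FHAD1-AS1 (4.95) lost it without radiation 1 or 2 or combination 1 (0.0666, 0.088 and 0.052) and LINC02301 (3.11) without radiation 1 (0.275). ZNF32-AS1 (4.85) lost it without vehicle 2 or 3, olaparib 1, radiation 1 or 2 or combination 1 or 3 (0.0567 to 0.223). SORD2P, FHAD1-AS1 and ZNF32-AS1, with 2 counts each in radiation, had ratios of 63.6 (95% counting interval 17.3 to 530), 34.1 (9.11 to 286) and 31.4 (8.36 to 264). Of the falls, COL8A1 (-0.93) lost it without radiation 1 (0.0591). MT-TE (-0.93) lost it without olaparib 1, radiation 1 or 2 or combination 2 or 3 (0.0553 to 0.166). KCNJ5 (-1.62) lost it without vehicle 1 or 2, olaparib 1, radiation 1 or 2 or combination 1, 2 or 3 (0.054 to 0.367). The genes named whatever their values were not called, with changes of -0.10 for PARP1 (SE 0.085, adjusted p = 0.777), 0.90 for CDKN1A (SE 0.575, adjusted p = 0.66), 1.87 for STING1 (SE 1.38, adjusted p = 0.728), 0.00 for CGAS (SE 0.123, adjusted p = 1), 0.14 for CD274 (SE 1.9, adjusted p = 0.996) and -0.34 for CCL5 (SE 1.55, adjusted p = 0.98).

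Combination versus olaparib asks what radiation added to the drug, again against olaparib 1 alone in the 9 libraries. Mitochondrially encoded mRNAs were lower, 12 of 13 over all genes and over the list alone (median log2 -0.65, adjusted p = 5.31e-40, and adjusted p = 0.00184 with an estimated correlation), as were histone genes, 10 of 18 over all genes and 13 over the list alone (median -0.78, adjusted p = 2.29e-27, and adjusted p = 0.0337 with an estimated correlation). Ribosomal protein genes had 1 higher and 28 lower, 1 and 36 over the list alone (-0.53, adjusted p = 5.19e-46, but adjusted p = 0.0845 with an estimated correlation). IGF2 was higher (2.01, SE 0.207, adjusted p = 4.38e-11), as in the 12 libraries, and SLC7A5 too (1.14, SE 0.233, adjusted p = 0.00103). PARP1 was lower (-0.40, SE 0.105, adjusted p = 0.0225), a call lost without combination 1 or 3 (0.0935 and 0.121).

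Genes called in combination versus olaparib by edgeR numbered 129 higher and 476 lower (3084 at an unadjusted p under 0.05; DESeq2 199 and 565, limma-voom 162 and 629; 227 and 149 with the covariate, and 306 and 215 under library size only). Cholesterol genes (5 lower, 7 over the list alone, -0.32, adjusted p = 8.94e-07), stress response genes (3 higher, 4 over the list alone, 0.10, adjusted p = 0.0013) and hypoxia genes (5 lower, 8 over the list alone, median -0.20, mean 0.04, adjusted p = 2.3e-06) were called by the preset test, with adjusted p = 0.153, 0.56 and 0.254 with an estimated correlation. G2/M genes (-0.04, adjusted p = 0.0221), AU-rich element binding genes (-0.14, adjusted p = 0.00236) and translation initiation genes (-0.22, 2 higher and 6 lower, adjusted p = 0.000754) were too, with adjusted p = 0.747, 0.285 and 0.609 with an estimated correlation. With all 12 libraries, 6 of these medians had the opposite sign and were called: ribosomal 0.211 (adjusted p = 6.16e-05), cholesterol 0.258 (0.00461), hypoxia 0.355 (1.11e-05), G2/M 0.471 (5.23e-14), AU-rich element binding 0.42 (7.8e-08) and translation initiation 0.386 (2.6e-09). The stress response list kept its sign (0.603), and the mitochondrial and histone lists kept theirs without a call (adjusted p = 0.889 and 0.274). With the covariate and the same 12 libraries, ribosomal (-0.328) and cholesterol genes (-0.169) were called as lower. Translation initiation and hypoxia genes then kept their sign without a call (-0.0685 and -0.0205), while G2/M and AU-rich element binding genes turned (0.076 and 0.04; not called). With library size only, G2/M (0.93), AU-rich element binding (0.391) and translation initiation genes (0.37) were not called. The stress response call was lost with the replicate block (0.0812) and with no count filter (0.0561). G2/M genes also lost theirs with the stricter filter (0.148), the replicate block (0.0512), the length offset (0.137), the GC offset (0.0755) and without combination 1 (0.163). The largest rises included the pseudogene HNRNPCP1, absent from olaparib 1 and at 1.68 CPM (SD 0.333, n = 3) in the combination, which is at least 21.4-fold higher with a floor of 3 counts per library. Others were ACSM2B (2.64, SE 0.51, adjusted p = 0.000395; -1.35 with all 12 libraries, adjusted p = 0.288) and the noncoding RNA LINC00279 (3.49, SE 0.92, adjusted p = 0.0215). The adaptor of Toll-like receptors MYD88 (4.46, adjusted p = 0.0435; 2 counts in olaparib 1, ratio 23.8, 95% counting interval 6.38 to 200) lost its call without vehicle 1, 2 or 3 or combination 1 or 2 (0.0566 to 0.0839), and PRDM11 (2.58) without vehicle 1 or 2 or combination 3 (0.0522, 0.0508 and 0.18). The falls all lost their call when 1 library was left out. PDCD6-AHRR, a readthrough transcript at 1.92 CPM in olaparib 1 and absent from the combination, at least 13.6-fold lower on the same floor, lost it without combination 1, 2 or 3 (0.117, 0.11 and 0.111). KPNB1-DT (-4.17) lost it without vehicle 1 or 3 or combination 1, 2 or 3 (0.0524 to 0.0874). PAQR9 (-1.56) lost it without combination 1 or 2 (0.0536 and 0.0936), MT-TL2 (-1.54) without combination 3 (0.0617), and the histone H3C3 (-1.56) without vehicle 2 or 3 or combination 1 or 3 (0.0546 to 0.157). CDKN1A (1.10, SE 0.75, adjusted p = 0.723), STING1 (0.36, SE 1.61, adjusted p = 0.992), CGAS (0.25, SE 0.157, adjusted p = 0.665), CD274 (0.73, SE 2.49, adjusted p = 0.986) and CCL5 (-1.15, SE 1.83, adjusted p = 0.947) were not called.

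The interaction asks whether the effect of radiation differed with olaparib present. EGR1 fell after either treatment, and its change in the combination was less than the sum of both: the interaction was 1.47 (SE 0.247, adjusted p = 0.000483). That of IGF2 was 1.02 (SE 0.242, adjusted p = 0.0406). Both were picked after their values were seen. By edgeR, 30 genes were higher and 32 lower than the sum of the single effects in the 9 libraries (2223 at an unadjusted p under 0.05; DESeq2 51 and 117, limma-voom 36 and 98), and 0 with the covariate and 12 libraries (2369 at an unadjusted p under 0.05). The total of 62 was 29 without radiation 1, 194 without radiation 2 and 126 without vehicle 3, and has no value without olaparib 1. Ribosomal protein genes had a median interaction of -0.39 (1 higher and 5 lower over all genes, 1 and 26 over the list alone; adjusted p = 4.45e-18), histone genes -0.47 (1.82e-07), cholesterol genes -0.19 (0.000834), G2/M genes -0.19 (4.92e-06), DNA replication genes -0.17 (0.0121) and hypoxia genes -0.25 (mean 0.02, 4.92e-06). Mitochondrially encoded mRNAs had a median of 0.25 (0.0159), a call lost without radiation 2 (0.095). None of the 7 held with an estimated correlation (adjusted p = 0.343 to 0.628), and with all 12 libraries 6 of the 7 medians had the opposite sign and were called. These were ribosomal 0.427 (adjusted p = 1.24e-08), histone 0.38 (0.000638), cholesterol 0.464 (0.000162), G2/M 0.467 (8.41e-10), DNA replication 0.389 (9.69e-05) and hypoxia 0.448 (5.14e-05). With the covariate and the same 12 libraries, all 7 kept the 9-library sign. Ribosomal (-0.294), histone (-0.32), hypoxia (-0.177) and mitochondrial genes (0.287) stayed called, while cholesterol (-0.0993, adjusted p = 0.157), G2/M (-0.128, adjusted p = 0.0548) and DNA replication genes (-0.106, adjusted p = 0.167) did not. DNA replication genes also lost theirs without radiation 1 (0.609) or combination 1 (0.101). PARP1 (-0.15, SE 0.136, adjusted p = 0.889), CDKN1A (0.43, SE 0.924, adjusted p = 0.98), CD274 (-1.09, SE 2.97, adjusted p = 0.99), CGAS (0.03, SE 0.198, adjusted p = 1), STING1 (-0.23, SE 1.98, adjusted p = 1) and CCL5 (-1.77, SE 2.39, adjusted p = 0.951) were not called.

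Of the genes called after radiation and in the combination, 93 were higher and 167 lower in both. Each response uses the same vehicle libraries, so unchanged groups also share calls and correlate: 20 simulated draws of these shared at most 5 higher and 4 lower calls. Independent lists of the observed sizes, which leave out the shared vehicle, would share 1.99 and 6.85. The 3 vehicle libraries are too few to split, so part of the excess may come from them. Across genes, which are not independent replicates, the log2 changes of radiation and of the combination had a Pearson r of 0.395 with 9 libraries, against a mean of 0.421 in 20 such draws, and a covariance of 0.612 against 0.457. Olaparib and the combination gave 0.303 against 0.325 (covariance 0.523 against 0.462), with 2 higher and 13 lower in both (at most 3 and 4 in the draws). Radiation and olaparib gave 0.323 against 0.303 (0.658 against 0.487), with 2 and 12 (at most 4 and 3). With 12 libraries the last pair had 0.842 against 0.496, as both groups hold libraries set aside. The other pairs had 0.331 against 0.487 and 0.251 against 0.493. The 12-library spread takes in the 3 libraries set aside, so r below the draws is not interpreted. Each of the 3 r values moved by more than 1.5 times when a library was left out.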

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

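The tests of transcript length, of exon number and cell markers over all annotated exons, of olaparib treatment, of normalization and of length offsets were chosen only after the result was seen, and all that follows on the interaction uses the 9 libraries, also chosen after seeing the data.

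The effect of radiation differed with and without olaparib, by the edgeR test of the interaction itself, for 10 genes that the naming rule picked. Higher than the sum of the single effects were HNRNPCP1 (log2 8.32, SE 1.94, adjusted p = 0.0334), SORD2P (7.16, SE 1.14, adjusted p = 0.000153), MYD88 (6.47, SE 1.5, adjusted p = 0.032), LINC02301 (4.80, SE 1.13, adjusted p = 0.0372) and ACSM2B (3.51, SE 0.61, adjusted p = 0.000547). Lower were RPS26 (-1.30, SE 0.293, adjusted p = 0.0223), LINC02154 (-0.94, SE 0.18, adjusted p = 0.00292), RPL9 (-0.77, SE 0.145, adjusted p = 0.00292), PSMA2 (-0.77, SE 0.162, adjusted p = 0.0106) and HMGN4 (-0.74, SE 0.146, adjusted p = 0.00448). Olaparib 1 is the lone olaparib library, assumed to vary like the other groups. HNRNPCP1 had no count and MYD88 2 counts in it, and SORD2P had 2 counts in radiation. The fitted 8.32, 6.47 and 7.16 and their SEs depend on the prior count. HNRNPCP1, SORD2P, RPS26 and RPL9 share sequence with related genes or pseudogenes. MYD88, which passes on Toll-like receptor signals, stood at 1.22 CPM in vehicle, 0.0526 in olaparib, 0.298 in radiation and 1.25 in the combination.

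Of these 10 genes, SORD2P and ACSM2B kept the call in each of the fits that left out 1 of the 9 libraries. None of the 10 passed with all 12 libraries or with the background covariate, where SORD2P had 5.21 (adjusted p = 0.142) and 6.46 (0.053). With all 12 libraries ACSM2B had -1.22, LINC02301 -1.13, LINC02154 0.0298, RPL9 0.109 and HMGN4 0.0893, each opposite in direction, and with the covariate ACSM2B had 2.84 (adjusted p = 0.065). Without radiation 1 the call was lost for the 8 besides SORD2P and ACSM2B (adjusted p = 0.0602 to 0.141). It was also lost for HNRNPCP1 without vehicle 1 or combination 1 or 3 (0.0597 to 0.128), for MYD88 without vehicle 1 or 2 or combination 1 or 2 (0.0606 to 0.0846), and for LINC02301 without vehicle 1 or 2 or combination 1, 2 or 3 (0.0597 to 0.12). RPS26 lost it without vehicle 2 (0.12) or combination 1 (0.106), and PSMA2 without combination 3 (0.0563). Groups of 3 libraries were not tested for single libraries far from the others.

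The counts of silent genes in olaparib 2, olaparib 3 and radiation 3 may come from genomic DNA. Among 1848 protein-coding genes nearly silent in the other 9, counts rose with transcript length in each of the 3 (lowest Spearman rho 0.346). RNA can give this too, so it does not point to DNA. A test written before its result argued against DNA, which would give a ratio of 0.5 to 2. Genes with 1 exon had 0.401 times the median counts per kb of those with several in olaparib 3. The ratio was 0.393 in olaparib 2 and 0 in radiation 3. The test used the median transcript length, which understates the sequence DNA reads can match in genes with many isoforms. With the mean over all annotated exons the ratio was 0.654 to 0.668, inside those bounds. The ratio of means on the first length was 0.46 to 0.478, under 0.5, so the result turns on the length chosen. The pre-written marker test for RNA of another cell type could not judge radiation 3, where the reference olfactory receptor median was 0. In olaparib 2 and 3 its lowest ratios were 6 (fibroblast, 5 genes), 5.19 (airway), 4.04 (leukocyte) and 2.49 (endothelium), read as undecided once seen. A later test used all annotated exons and silent genes with several exons as reference. All 4 lists then reached 2.14 times at most, under the 5 set for that source. These changes were not separated, so this source stays open. Olaparib does not explain the signal: olaparib 1 and the combination reached 500.9 CPM at most against 914.5 in radiation 3, without olaparib. The exon tests disagree, and the origin stays open.

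In the 9 libraries, lower mitochondrially encoded mRNAs after radiation held in the settings tried. The list median was -0.634 with library size only (quartiles -0.786 and -0.583). It was -0.745 with libraries thinned to about the smallest total (-0.889 and -0.69). With length offsets the list median was -0.731 (-0.841 and -0.674). Mitochondrial ribosomal RNA fell less, to 34.1% and 34.8% of counts from 35.5% to 36.8%. MT-RNR2 (31.1% and 31.4%) stayed within vehicle (30.2% to 32.2%). A lower mitochondrial mRNA level after irradiation stays a hypothesis, as it was found and tested on the same data. Library preparation that follows the groups was not tested.

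For lower ribosomal protein and histone mRNAs in combination versus vehicle in the 9 libraries, normalization is not settled for the ribosomal list: with library size only its median went from -0.385 to -0.183 (quartiles -0.286 and -0.102), while that of the histone list was -0.436 (-0.676 and -0.175). With transcript length offsets the medians were -0.315 for the ribosomal list (quartiles -0.389 and -0.227) and -0.602 for the histone list (-0.78 and -0.363), and with thinned libraries, for library depth, -0.397 (-0.496 and -0.313) and -0.631 (-0.896 and -0.41). Adding the counts of 469 pseudogenes to their parents gave -0.396 for the ribosomal list (-0.481 and -0.286). An effect of the treatment on histone mRNAs stays a hypothesis. For the ribosomal list how much is left without the scaling stays open, and its call was lost with an estimated correlation (adjusted p = 0.0795).

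Other splits of the same libraries were counted. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In the 12-library fits, genes called were 1 in combination versus vehicle (highest of the other splits 0; 1 split of 10 as large), 0 in radiation versus vehicle (2; 10), 0 in olaparib versus vehicle (1456; 10), 0 in combination versus radiation (1; 10) and 3 in combination versus olaparib (0; 1). The edgeR counts at an unadjusted p under 0.05 for the comparisons with 0 calls were 1358, 9369 and 1044, with 26, 3762 and 4 calls by DESeq2 and 0 by limma-voom. The split with 1456 calls set olaparib 2, olaparib 3 and vehicle 1 against the others and points to a structure of the samples. Lists called were 6 (highest other 6; 3 of 10), 7 (17; 8), 18 (17; 1), 0 (14; 10) and 15 (17; 4) in the same order. In the 9-library fit of combination versus vehicle, 1485 genes (3; 1) and 8 lists (7; 1) were called, and in the 6-library fit 1494 genes (2; 1). For the interaction with 12 libraries all 100 groupings drawn gave at least the 0 genes of the real one (highest other 5; 7747 at an unadjusted p under 0.05, 1792 by DESeq2, 0 by limma-voom). With a real count of 0 every grouping gives at least as many, so that comparison, like each above with a real count of 0, says nothing about chance.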

How the results depend on the processing

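The 9-library fits, the fits with all 12 libraries beside them, the background covariate and the length and GC offsets were chosen after seeing the data, as were all alternatives run on the 9 libraries. Settings not named for a result gave counts within 1.5 times of it. The cause of each change was not tested, apart from the fewer libraries in a fit.

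For combination versus vehicle, 1 gene called with 12 libraries became 390 with library size only, 102 with no count filter, 2 with the stricter filter, 98 with DESeq2, 0 with limma-voom, 1494 with the compared groups only, 0 with the replicate block, 1485 without the 3 libraries with high background and 831 with the background covariate. For radiation versus vehicle, 0 genes became 16 with library size only, 261 with no count filter, 26 with DESeq2, 49 with the compared groups only, 340 without the 3 libraries and 194 with the covariate. For olaparib versus vehicle, 0 became 1 with library size only, 4433 with no count filter, 3762 with DESeq2, 21 without the 3 libraries and 10 with the covariate. For combination versus radiation, 0 became 256 with no count filter, 4 with DESeq2, 1 with the compared groups only, 176 without the 3 libraries and 28 with the covariate. For combination versus olaparib, 3 became 472 with library size only, 4303 with no count filter, 3703 with DESeq2, 1 with limma-voom, 0 with the compared groups only, 1 with the replicate block, 605 without the 3 libraries and 376 with the covariate. For the interaction, 0 became 4620 with no count filter, 1792 with DESeq2 and 62 without the 3 libraries. The edgeR counts at an unadjusted p under 0.05 beside the counts of 0 were 1358, 9369, 1044 and 7747.

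In the 9 libraries, 1485 genes in combination versus vehicle became 2594 with library size only, 1 with all 12 libraries, 831 with the covariate and 135 with an absolute log2 change of at least 1. The 340 in radiation versus vehicle became 685 with library size only, 190 with the compared groups only, 0 with all 12 libraries, 194 with the covariate and 45 at a log2 of at least 1. The 21 in olaparib versus vehicle became 39 with no count filter, 40 with DESeq2, 46 with limma-voom, 37 with the compared groups only, 43 with the replicate block, 0 with all 12 libraries, 10 with the covariate and 11 at a log2 of at least 1. The 176 in combination versus radiation became 278 with no count filter, 423 with DESeq2, 64 with the compared groups only, 0 with all 12 libraries, 28 with the covariate and 27 at a log2 of at least 1. The 605 in combination versus olaparib became 3 with all 12 libraries, 376 with the covariate and 67 at a log2 of at least 1. The 62 for the interaction became 130 with no count filter, 168 with DESeq2, 134 with limma-voom, 103 with the replicate block, 0 with all 12 libraries, 0 with the covariate and 20 at a log2 of at least 1.

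Leaving out each library in turn with 12 libraries gave 0 to 240 genes in combination versus vehicle, 0 to 59 in radiation versus vehicle, 0 to 18110 in olaparib versus vehicle, 0 to 2 in combination versus radiation, 0 to 17267 in combination versus olaparib and 0 to 16020 for the interaction. The highest came without olaparib 1, except 2 without radiation 3. With 9 libraries the ranges were 1030 (without combination 3) to 1716 (without radiation 2), 200 (without vehicle 2) to 360 (without combination 1), 18 (without vehicle 2) to 33 (without vehicle 3), 38 (without radiation 1) to 447 (without radiation 2), 458 (without combination 3) to 722 (without radiation 2) and 29 (without radiation 1) to 194 (without radiation 2). Without olaparib 1 no olaparib library is left among the 9, so its comparisons gave no value there.

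List tests called moved as follows. In olaparib versus vehicle, 18 became 3 without the 3 libraries and 1 with the covariate; in combination versus radiation, 0 became 3 with library size only, 8 without the 3 libraries and 5 with the covariate; in combination versus olaparib, 15 became 9 and 5, and for the interaction 17 became 7 and 4. With 9 libraries, 3 in olaparib versus vehicle became 9 with library size only, 5 with no count filter, 6 with the replicate block, 1 with structural RNA left out, 18 with all 12 libraries, and 1 with the covariate, the length offset or the GC offset. The 8 in combination versus radiation became 4 with library size only, 0 with all 12 libraries and 5 with the covariate, the 9 in combination versus olaparib 15 and 5, and the 7 for the interaction 17 and 4. Leaving out 1 library gave 5 to 9, 4 to 17, 17 to 19, 0 to 8, 11 to 18 and 14 to 20 lists with 12 libraries, in the order of the gene counts, and 7 to 8, 5 to 6, 1 to 8, 5 to 10, 8 to 10 and 6 to 10 with 9. Of those, 17 came without radiation 1 and 4 without radiation 3, and with 9 libraries 1 came without vehicle 1 and 8 without vehicle 3.

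Medians of lists changed sign in some settings. In combination versus vehicle, G2/M genes had 0.176 with library size only and 0.0763 with the covariate, with either set of libraries. AU-rich element binding genes had 0.0701 with library size only and 12 libraries and 0.0712 with 9. With 9 libraries, translation initiation had 0.0542 and hypoxia 0.121 with library size only, and hypoxia 0.0261 with the covariate. In radiation versus vehicle with 12 libraries, G2/M genes had 0.166 with library size only, 0.079 without the 3 libraries and 0.176 with the covariate, and AU-rich element binding genes 0.011 with library size only and 0.0211 with the covariate. Translation initiation had 0.00521 and hypoxia 0.0895 with the covariate, and with 1 library left out DNA replication genes went from -0.0598 (without radiation 1) to 0.11 (without radiation 3), DNA repair genes from -0.0642 (without radiation 1) to 0.035 (without radiation 3) and the PARP family from -0.0981 (without radiation 1) to 0.0724 (without radiation 3). With all 12 libraries in place of 9, G2/M genes had -0.00335 in radiation versus vehicle, and olaparib versus vehicle had -0.5 for G2/M, -0.578 for ribosomal, -0.601 for histone and -0.392 for stress response genes. Chemokines there went from 3.53 with 12 libraries to -0.412 with the covariate. Combination versus radiation then had 0.00519 for G2/M, 0.0249 for AU-rich element binding (0.0179 with library size only) and 0.0274 for translation initiation genes, and combination versus olaparib 0.211 for ribosomal, 0.258 for cholesterol, 0.471 for G2/M, 0.42 for AU-rich element binding, 0.386 for translation initiation and 0.355 for hypoxia genes. In that comparison G2/M had 0.0838 with library size only and 0.076 with the covariate, and AU-rich element binding 0.04 with the covariate. The interaction had -5.32 for chemokines, 0.427 for ribosomal, 0.38 for histone, 0.403 for stress response, 0.464 for cholesterol, 0.389 for DNA replication, 0.467 for G2/M and 0.448 for hypoxia genes.

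Named genes that changed sign with all 12 libraries in place of 9 were ACSM2B in olaparib versus vehicle (1.19), MYD88 (-0.29), LINC00279 (-1.94), ACSM2B (-1.35), PRDM11 (-1.19) and PARP1 (0.20) in combination versus olaparib, and LINC02301 (-1.13), ACSM2B (-1.22), LINC02154 (0.0298), RPL9 (0.109) and HMGN4 (0.0893) in the interaction. Over all alternatives for named genes with 9 libraries, 3059 values kept direction and call or had no call in either fit, whatever their sign. Of the others, 416 kept direction but lost the call, 40 gained it and 11 changed sign with a call in either fit. For a selection of 104 list medians, not all, these numbers were 1802, 62, 36 and 32. The correlations of responses changed with the covariate to 0.493 (radiation and combination), 0.521 (olaparib and combination) and 0.62 (radiation and olaparib). With no count filter radiation and olaparib gave 0.582 with 12 libraries and 0.427 with 9, olaparib and combination 0.417 with 9, and radiation and olaparib 0.323 without the 3 libraries and 0.842 with all 12. Leaving out 1 library gave 0.282 to 0.503, 0.158 to 0.428 and 0.116 to 0.83 with 12 libraries, and 0.264 to 0.523, 0.286 to 0.42 and 0.282 to 0.422 with 9. At this depth, a count of 0 allows 0.0788 to 0.146 CPM among the 9. The simulation recovered 31.3% of 1.5-fold changes in combination versus vehicle with 9 libraries and 0% with 12, not split by expression level.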
